A study of Mus musculus with 6 samples.

How the data were processed

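RNA was measured in 6 bladder tumours of female mice, all treated with an anti-PD-1 antibody after tumours had formed in an immunocompetent model of spontaneous bladder cancer. The labels place 3 tumours in a non-responsive and 3 in a responsive group, and the response status is the authors' own. Per the labels' protocols, total RNA was extracted with TRIZOL and libraries were made with an Illumina TruSeq RNA kit. Per the submitters' processing notes the genome build was mm10. The aligner, the counting tool, its strand setting and the annotation are not given in the sources used here.

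The deposited table holds, per the file headers, an estimated count and an FPKM value per gene and tumour. The estimated counts (expected counts) the authors deposited are not normalised between tumours, and 8.19 to 9.99% of the values per tumour were not whole numbers. The FPKM values the authors deposited are scaled for gene length and sequencing depth. The counts were rounded to whole numbers and used for every main result, and FPKM values entered an alternative only. The table lists 22063 genes, of which 21973 have an identifier in GENCODE mouse release 21, an annotation of the same build from which gene coordinates were taken. Coordinates count from 1. The 30 rows without a gene symbol held at most 0.000216% of a tumour's counts and were kept as identifiers.

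Total counts were between 15046180 and 23917398 per tumour. At this depth a count of 3, the upper limit that a count of 0 allows, equals 0.125 to 0.199 CPM, the count scaled by library size. This limit covers counting error only. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of 75.7 or more over genes with a count of at least 20 in the pair), so all 6 were used as separate samples.

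Before the data were examined, the comparison (non-responsive minus responsive), the tests, the gene lists and the rule for named genes were fixed. Genes were tested with edgeR 4.0.16 in R 4.3.3, using TMM normalisation, its default expression filter and the robust quasi-likelihood test. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 5%. The filter left 14505 genes. CPM values are TMM-normalised and given as mean ± SD over 3 tumours, and log2 fold changes are given with their standard error. The 31 gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, for lists with at least 5 genes tested, and adjusted over the lists. A list score is the mean, over the list's genes, of log2 CPM (prior count 2) minus the gene's mean over the 6 tumours. Scores and quality measures of single values were compared with two-sided exact permutation tests, which cannot give a p below 0.1 for 3 against 3.

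Genes are named by this rule. First come up to 10 genes per direction with the largest change among those past the threshold and at an average log2 CPM of at least 1. If fewer pass, genes of the smallest unadjusted p fill up to 5 per direction, leaving out gene-model placeholders and antigen receptor segments. Then come up to 4 members, of smallest p in the list's direction, from each list past its threshold. The genes Pdcd1, Cd274, Cd8a, Cd3e, Cd4, Gzmb, Ifng, Foxp3, Cxcl9, Tgfb1, Mki67, Krt5 and Upk2 are always given. Members at an unadjusted p under 0.05 against the direction of a list past its threshold were added after the results were seen. Some macrophage markers that differed little or ran against their list were added too. Some genes that the rule selects are not reported here.

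Alternatives for the genes were DESeq2 size factors or upper quartile scaling in edgeR, the DESeq2 1.42.0 test, limma-voom with quality weights, no filter, a stricter filter of at least 5 CPM in 3 tumours, a minimum fold of 2, the replicate number as a block, and leaving out each tumour. Lists were also tested with an estimated correlation, with fry and on ranks. Added after the data were seen were the edgeR likelihood ratio test, limma on log2(FPKM + 1) for genes with an FPKM of at least 1 in 3 tumours, DESeq2 without each tumour and the single lists under each setting. Of the genes DESeq2 examined, 3265 had no adjusted p and were left as missing.

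The gene test was tested on simulated data, with counts for 14505 genes drawn from the means and library sizes of these groups. Known changes were added only to some genes with a mean of at least 5 CPM, so the shares called do not hold for genes at lower counts. edgeR called 7.5% of 80 genes changed 2-fold, 60% of 80 changed 4-fold and 97.5% of 40 changed 8-fold, with 8 false calls. DESeq2 called 35%, 86.25% and 100% of them, with 58 false calls. In another draw of this kind camera found a raised list. It called 0 of 30 random lists, but the simulated genes varied independently, while the gene lists had a median estimated correlation of 0.521, so this check says nothing about false list calls in these tumours.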

Results

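The transcriptomes of 6 bladder tumours from female mice treated with an anti-PD-1 antibody were measured by bulk RNA sequencing. PD-1 is an inhibitory receptor of T cells, and blocking it can restore T cell activity against a tumour. According to the labels, 3 tumours were non-responsive and 3 responsive. Total counts were 17153992, 15046180 and 19943246 in non-responsive replicates 1, 2 and 3, and 23188207, 16545079 and 23917398 in responsive replicates 1, 2 and 3. The means were 17381139 ± 2456422 and 21216895 ± 4062306 (SD, n = 3 per group; exact permutation p = 0.3). Genes with a count numbered 16502 ± 118 in the non-responsive and 16824 ± 159 in the responsive tumours, without overlap (exact permutation p = 0.1, the smallest possible). Mitochondrial genes took 3.42, 6.39 and 8.08% of the counts in the non-responsive and 5.37, 4.79 and 4.77% in the responsive tumours. The labels give separate samples, but nothing says that they came from separate animals, so p-values measure the spread between these samples, which may be technical.

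The first principal component of log2 CPM held 35.1% of the variance. The responsive tumours lay at -31.6, -36.3 and -50.9 on it, and non-responsive replicates 2 and 3 at 55.6 and 64.9. Non-responsive replicate 1 lay between them at -1.67. Its highest correlation over genes was with responsive replicate 2 (Pearson r = 0.950), against 0.906 and 0.921 with non-responsive replicates 2 and 3. With responsive replicates 1 and 3 the correlation was 0.914 and 0.916. On the second component non-responsive replicate 1 lay at -55.4 and the responsive tumours at 16.0, -1.68 and 15.6. Non-responsive replicates 2 and 3 lay there at 54.4 and -28.9.

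**Figure D1:**
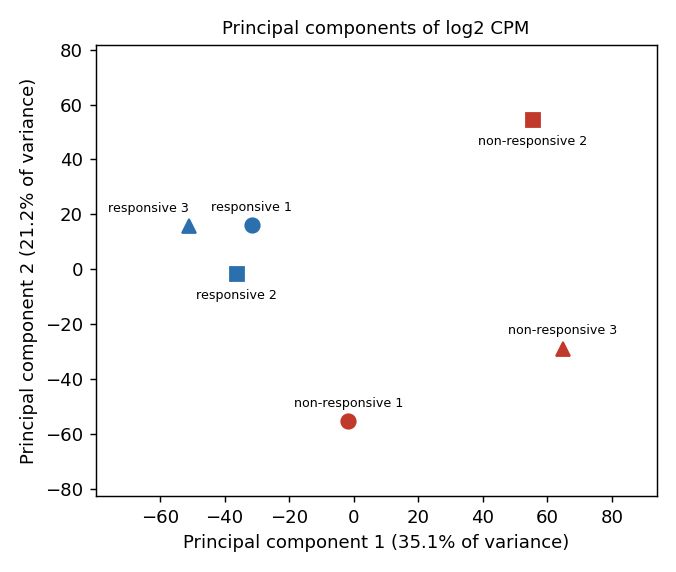
Each point is a tumour, placed by its first (horizontal) and second (vertical) principal component of log2 CPM, which hold 35.1% and 21.2% of the variance. Colours mark the response group and shapes the replicate number; non-responsive replicate 1 lies at -1.67 on the first component, between the responsive tumours and the other non-responsive tumours.

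The comparison of non-responsive with responsive tumours asks which genes differ in expression with resistance to checkpoint blockade, with T cell dysfunction as the study's stated interest. Non-responsive tumours had higher levels of the lists of TGF-beta, cytotoxic and macrophage genes, and lower levels of luminal urothelial, mast cell and adipocyte genes. With an estimated correlation these calls were lost (adjusted p = 0.302 for TGF-beta and 0.539 for each of the others). The adipocyte median rested on responsive replicate 1, with -3.81 over all tumours and -1.09 without it. Endothelial and matrix lists were also higher, although non-responsive replicate 1 scored within the responsive range on both (adjusted p = 0.539 for each with an estimated correlation). The T cell list was higher with all 6 tumours, but without non-responsive replicate 2 its median was 0.36 and the call was lost (camera adjusted p = 0.0784). With an estimated correlation the T cell call was also lost with all 6 tumours (adjusted p = 0.582). Under the stricter filter the T cell and cytotoxic lists had too few genes to be tested. Luminal urothelial genes were a median 3.20-fold lower and cytotoxic effector genes a median 2.57-fold higher. The cytotoxic median log2 fold change was 1.36 over all tumours and 0.96 without non-responsive replicate 2. Of 31 lists, 21 passed the camera test, 15 higher and 6 lower in non-responsive tumours, while the other splits of the same tumours into 3 and 3 gave 14 to 22 lists. Among the 21 lists the tumour scores of the groups did not overlap for luminal urothelial, cytotoxic, TGF-beta, macrophage, T cell, naive and memory T cell and skeletal muscle genes (exact permutation p = 0.1 each, the smallest possible), and overlapped for all others. For naive and memory T cell genes the groups nearly touched, with non-responsive replicate 1 at -0.179 and responsive replicate 2 at -0.181. For luminal genes non-responsive replicate 1 was at -0.22 and responsive replicate 1 at -0.18. None of the 31 passed with an estimated correlation (smallest adjusted p = 0.302, with 2 lists at an unadjusted p under 0.05) or by fry (smallest adjusted p = 0.140, with 2 lists at an unadjusted p under 0.05), against 22 by camera on ranks.

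No single gene passed the edgeR quasi-likelihood test: 0 genes were higher and 0 lower, and the smallest adjusted p was 0.350. At an unadjusted p under 0.05 there were 1825 of 14505 genes, 985 higher and 840 lower, against 263 to 1571 in the other splits of the 6 tumours into 3 and 3. The count was 3469 without non-responsive replicate 1, 1144 without non-responsive replicate 3 and 1185 without responsive replicate 3. DESeq2 called 447 genes, 217 higher and 230 lower (4 to 307 in the other splits), limma-voom called 0, limma on FPKM 0 and the edgeR likelihood ratio test 212. Without non-responsive replicate 1 DESeq2 called 1966 genes, without non-responsive replicate 3 it called 169, without responsive replicate 2 it called 293 and without responsive replicate 3 it called 192. The 3 non-responsive values lay all above or all below the 3 responsive values for 2562 genes (17.7%, against 10% by chance).

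The 5 genes of smallest unadjusted p in each direction had an edgeR adjusted p of 0.35 and none passed, while all 10 were among the DESeq2 calls. At higher levels in non-responsive tumours were Itga5, Vcam1, Timp3, Vcan and Loxl2, and at lower levels Prss8, Mgst3, Gsta3, Nabp1 and Pmm1. Itga5 (chromosome 15, 103344286 to 103366763), the alpha chain of a fibronectin receptor, was at 140 ± 24.4 CPM in non-responsive and 47.5 ± 4.97 CPM in responsive tumours (SD, n = 3), a log2 difference of 1.56 ± 0.20 (SE). Vcam1 (chromosome 3, 116109949 to 116129688), an adhesion molecule that binds leukocytes, was at 109 ± 7.56 against 42.9 ± 5.27 CPM (1.34 ± 0.18). Timp3 (chromosome 10, 86300372 to 86349506), an inhibitor of metalloproteinases, was at 482 ± 18.3 against 174 ± 17 CPM (1.47 ± 0.20). Vcan (chromosome 13, 89655312 to 89742509), the matrix proteoglycan versican, had a log2 difference of 1.08 ± 0.17, and Loxl2 (chromosome 14, 69609068 to 69695834), which cross-links collagen, of 1.48 ± 0.23.

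Among the genes at lower levels, Prss8 (chromosome 7, 127925716 to 127930104), an epithelial membrane-anchored serine protease, was at 18.0 ± 3.88 CPM in non-responsive and 63.8 ± 5.77 CPM in responsive tumours (-1.83 ± 0.22). The glutathione transferases Mgst3 (chromosome 1, 167371966 to 167393841) and Gsta3 (chromosome 1, 21240589 to 21265661) had log2 differences of -1.69 ± 0.24 and -2.50 ± 0.39. Gsta3 has close paralogs, and how shared reads were counted is not given in the sources used here. Nabp1 (chromosome 1, 51465862 to 51478425), a single-strand DNA binding protein, and Pmm1 (chromosome 15, 81951108 to 81960930), a phosphomannomutase, had log2 differences of -1.32 ± 0.22 and -1.16 ± 0.20.

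**Figure D2:**
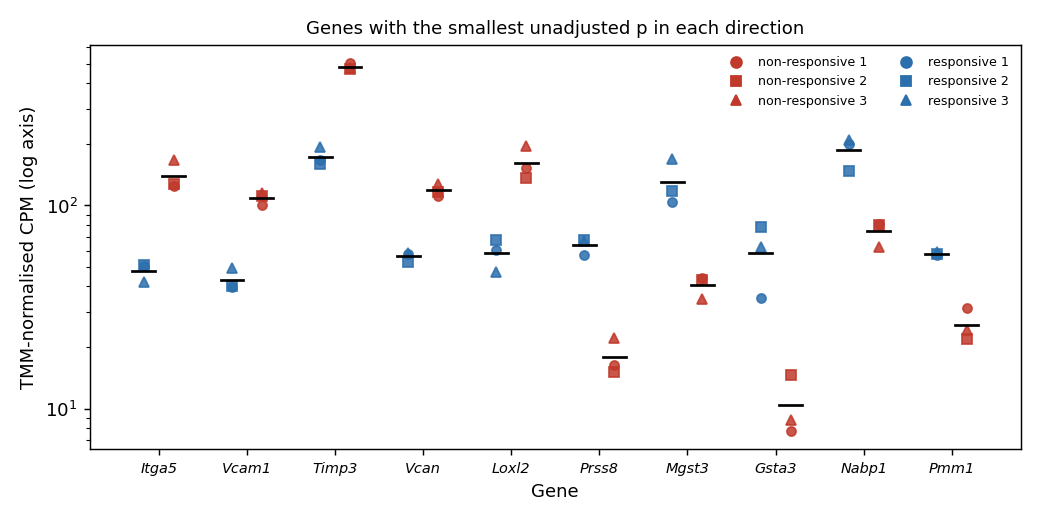
TMM-normalised CPM (vertical, log axis) of the 10 genes with the smallest unadjusted p, 5 per direction, in each tumour. Colours mark the response group, shapes the replicate number and black lines the group means; Itga5 has means of 140 and 47.5 CPM and Prss8 of 18.0 and 63.8 CPM in non-responsive and responsive tumours.

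Genes of T cells were higher in non-responsive tumours as a list, with all 18 T cell markers above 0 and a median log2 fold change of 1.47 (camera adjusted p = 6.59e-06; adjusted p = 0.582 with an estimated correlation). The list rested on non-responsive replicate 2, whose score was 2.02 against -0.15 and -0.25 in the other non-responsive tumours and -0.77 to -0.37 in the responsive ones. Without it the median was 0.36 (camera adjusted p = 0.0784). Cd8a, of the CD8 co-receptor, was at 6.06 ± 4.83 against 1.76 ± 0.846 CPM (SD, n = 3), a log2 difference of 1.79 ± 0.68 (SE), and its partner Cd8b1 differed by 1.79 ± 0.71. The costimulatory receptor Cd28 differed by 2.11 ± 0.86, Cd3e of the T cell receptor complex by 1.30 ± 0.72 and Cd4 by 1.23 ± 0.72. Without non-responsive replicate 2 the log2 differences were 0.94 for Cd8a, 1.12 for Cd8b1, 0.56 for Cd28, 0.12 for Cd3e and -0.050 for Cd4. None of the 18 passed edgeR over all genes or adjusted over the list alone.

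Cytotoxic effector genes were higher with all 12 tested members above 0 and a median of 1.36 (camera adjusted p = 2.83e-07; adjusted p = 0.539 with an estimated correlation). The list holds 18 genes, of which only these 12 passed the expression filter. Non-responsive replicate 2 had the highest score at 1.57, against 0.43 and -0.02 in non-responsive replicates 1 and 3. The responsive tumours scored -0.82 to -0.48. Without non-responsive replicate 2 the median was 0.96 (camera adjusted p = 0.000118). Over all genes 0 passed edgeR, and 7 passed adjusted over the list alone. Gzmb, encoding granzyme B, was at 4.49 ± 2.37 against 1.19 ± 0.186 CPM (1.91 ± 0.53). Prf1, encoding the pore-forming perforin, was at 1.66 ± 1.35 against 0.210 ± 0.149 CPM (2.90 ± 0.86). Its responsive values of 0.362, 0.0635 and 0.206 CPM lay near the limit that a count of 0 allows. The granule gene Nkg7 differed by 1.36 ± 0.45 and the chemokine receptor Cx3cr1, also on the macrophage list, by 1.37 ± 0.34. Without non-responsive replicate 2 Gzmb, Prf1, Nkg7 and Cx3cr1 differed by 1.44, 2.02, 1.12 and 1.04. Ifng was below the filter, with counts of 6, 22 and 12 in the non-responsive and 0, 5 and 2 in the responsive tumours.

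Inhibitory receptor and exhaustion genes had a median of 0.81, with 14 of 17 above 0 (camera adjusted p = 0.00974; adjusted p = 0.616 with an estimated correlation). Under the stricter filter the median was 0.45 and the call was lost (adjusted p = 0.125). Without non-responsive replicate 2 the median was 0.26 (adjusted p = 0.408), and without responsive replicate 3 it was 0.61 (adjusted p = 0.0963). Pdcd1, encoding PD-1, the target of the antibody, was at 6.62 ± 5.60 against 2.24 ± 0.502 CPM (1.55 ± 0.63). Tnfrsf9, a costimulatory receptor of activated T cells, differed by 1.91 ± 0.51, Ctla4 by 2.40 ± 0.94 and Btla by 1.58 ± 0.68. Without non-responsive replicate 2 Pdcd1 differed by 0.60, Ctla4 by 0.73 and Btla by 0.48. In the other direction Nr4a1, a transcription factor on this list, differed by -0.84 ± 0.27 (unadjusted p = 0.0157), the second smallest p of the list. Of this list 0 genes passed edgeR, over all genes or adjusted over the list alone.

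Regulatory T cell genes had a median of 1.29 (camera adjusted p = 0.00183; adjusted p = 0.550 with an estimated correlation), and 0.32 without non-responsive replicate 2 (adjusted p = 0.145). The stricter filter left too few of them to test. Their lineage factor Foxp3 differed by 2.05 ± 0.95, Icos by 1.92 ± 0.86, Il2ra by 1.74 ± 0.78 and Lrrc32, which presents latent TGF-beta, by 0.90 ± 0.39. Without that tumour Foxp3 differed by 0.21, Icos by 0.47, Il2ra by 0.32 and Lrrc32 by 0.56. Naive and memory T cell genes had a median of 0.83, with 9 of 12 above 0 (camera adjusted p = 0.0127; adjusted p = 0.582 with an estimated correlation), 0.32 without that tumour (adjusted p = 0.429) and 0.75 under the stricter filter (adjusted p = 0.0582). Cd27 differed by 2.59 ± 0.79, Il7r by 2.00 ± 0.72, S1pr1 by 1.26 ± 0.43 and Tcf7 by 0.93 ± 0.42. Cd27, Il7r, S1pr1 and Tcf7 differed by 1.47, 0.84, 1.10 and 0.57 without that tumour. S1pr1 was at 26.5, 76.5 and 82.9 CPM in non-responsive replicates 1, 2 and 3, while the T cell score was high in replicate 2 alone. B cell and plasma cell markers had a median of 1.12 (camera adjusted p = 0.00974; adjusted p = 0.675 with an estimated correlation), 0.11 without non-responsive replicate 2 (adjusted p = 0.931), 1.06 without responsive replicate 3 (adjusted p = 0.0536) and 1.48 under the stricter filter (adjusted p = 0.0525). The immunoglobulin genes Ighm and Igkc differed by 1.6 ± 0.76 and 1.52 ± 0.75, and the B cell genes Pax5 and Ms4a1 by 1.64 ± 0.80 and 1.52 ± 0.80. Without non-responsive replicate 2 these were 0.67, 0.44, 0.40 and 0.27. In these 3 lists 0 genes passed edgeR adjusted over the list alone.

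Macrophage and monocyte markers were higher in non-responsive tumours, with 16 of 17 above 0 and a median of 0.68 (camera adjusted p = 6.59e-06; adjusted p = 0.539 with an estimated correlation). Adjusted over the list alone 5 passed, and 0 over all genes. The Fc receptor Fcgr1 was at 44.6 ± 6.50 against 20.4 ± 6.91 CPM (1.13 ± 0.29), the scavenger receptor Msr1 differed by 1.31 ± 0.37 and Mertk, a receptor for apoptotic cells, by 1.23 ± 0.35. Other members differed little, with C1qa, C1qb, C1qc, Trem2 and Mrc1 at 0.11, 0.28, 0.27, 0.14 and 0.13. Cd163 differed by -1.23 ± 0.89. Without responsive replicate 3, which had a macrophage score of -1.30, the median was 0.48 (camera adjusted p = 0.0046). Neutrophil markers had a median of 0.53, with 14 of 15 above 0 (camera adjusted p = 0.0038; adjusted p = 0.582 with an estimated correlation). Their median was 0.37 without non-responsive replicate 1 (adjusted p = 0.206), 0.20 without responsive replicate 3 (adjusted p = 0.123), 0.35 without responsive replicate 1 (adjusted p = 0.039) and 1.70 without responsive replicate 2 (adjusted p = 6.48e-10). The granule genes Camp, Ngp and Ltf differed by 4.23 ± 1.65, 2.85 ± 1.39 and 1.90 ± 0.95, and Retnlg by 1.52 ± 0.67. In responsive replicate 1 Ltf was at 900 CPM with Camp and Ngp at 0.045 and 0.090 CPM, so Ltf did not follow them there. Retnlg differed by 0.78 without non-responsive replicate 2 and 2.40 without responsive replicate 2, where Ngp was at 4.48. Camp, Ngp and Ltf rested on non-responsive replicate 1, where Camp was at 26.6 CPM against 0.704 and 0.834 CPM in the other non-responsive tumours, and without it they differed by 0.63, 0.79 and 0.39.

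Interferon gamma response genes had a median of 0.64, with 15 of 17 above 0 (camera adjusted p = 6.1e-06; adjusted p = 0.539 with an estimated correlation), with 0.36 without non-responsive replicate 2 (adjusted p = 0.00518) and 1.04 without responsive replicate 2 (adjusted p = 2.3e-08). The T cell attracting chemokine Cxcl9 was at 127 ± 113 against 9.66 ± 6.17 CPM (3.73 ± 1.04) and Cxcl10 differed by 1.86 ± 0.56. In non-responsive replicate 1 Cxcl9 was at 14.2 CPM, within the responsive range of 2.84 to 14.9 CPM. The interferon-inducible GTPases Gbp4 and Iigp1 differed by 2.44 ± 0.64 and 1.89 ± 0.54. Of the interferon gamma list 0 genes passed edgeR adjusted over the list alone (smallest adjusted p = 0.0533). MHC class II genes had a median of 0.61 (camera adjusted p = 0.0222; adjusted p = 0.675 with an estimated correlation), which was -0.28 without non-responsive replicate 2 (adjusted p = 0.778), 0.53 without responsive replicate 3 (adjusted p = 0.0994) and 0.33 under the stricter filter (adjusted p = 0.0537). The protease Ctss differed by 1.48 ± 0.46, Cd86 by 0.92 ± 0.34, the class II transactivator Ciita by 1.07 ± 0.59 and H2-DMb2, which has a close paralog, by 0.99 ± 0.62. Without non-responsive replicate 2 Ciita differed by 0.070, H2-DMb2 by -0.016 and Cd86 by 0.61.

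Immunosuppressive mediators had a median of 0.62, with 10 of 15 above 0 (camera adjusted p = 0.0249; adjusted p = 0.539 with an estimated correlation). The median was 0.33 without non-responsive replicate 2 (adjusted p = 0.063), 0.37 without non-responsive replicate 3 (adjusted p = 0.0103), 0.43 without responsive replicate 3 (adjusted p = 0.261) and 0.44 under the stricter filter (adjusted p = 0.251). The PD-1 ligands Cd274 and Pdcd1lg2 differed by 1.48 ± 0.48 and 2.66 ± 0.87, with 1.21 for Pdcd1lg2 without non-responsive replicate 2, and the nitric oxide synthase Nos2 by 1.72 ± 0.48. Tgfb1 was at 89.6 ± 20.3 against 62.7 ± 8.85 CPM (0.51 ± 0.23).

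The TGF-beta pathway and its targets were higher in every non-responsive tumour, with scores of 0.33, 0.34 and 0.63 against -0.33, -0.28 and -0.69 in the responsive ones (exact permutation p = 0.1, the smallest possible). The median was 0.81 (camera adjusted p = 6.79e-07; adjusted p = 0.302 with an estimated correlation), 13 of 15 genes were above 0, and 7 passed adjusted over the list alone. Ltbp2, a latent TGF-beta binding protein family member, was at 57.3 ± 17.7 against 14.4 ± 6.86 CPM (1.99 ± 0.40). The receptor Tgfbr1 differed by 1.30 ± 0.33, and the target gene Tgfbi by 1.05 ± 0.33.

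Fibroblast and matrix genes had a median of 0.75 (camera adjusted p = 7.65e-05; adjusted p = 0.539 with an estimated correlation), with 13 of 16 above 0 and 8 past the threshold adjusted over the list alone. The collagen genes Col1a1, Col1a2 and Col5a1 differed by 1.06 ± 0.26, 1.02 ± 0.26 and 1.24 ± 0.31, and Fn1, encoding fibronectin, by 1.28 ± 0.39, while the proteoglycan gene Dcn differed by -1.08 ± 0.40 (unadjusted p = 0.0303). The matrix score of non-responsive replicate 1 was -0.16, within the responsive range of -0.51 to -0.05, and the other non-responsive tumours were at 0.54 and 0.43. Endothelial markers had a median of 1.02, with all 12 above 0 (camera adjusted p = 5.46e-06; adjusted p = 0.539 with an estimated correlation). The endothelial score of non-responsive replicate 1 was -0.60, within the responsive range of -0.72 to -0.12, and the other non-responsive tumours were at 1.08 and 0.86. Kdr, a VEGF receptor, differed by 1.02 ± 0.33, Robo4 by 1.42 ± 0.46, the junction gene Cdh5 by 1.66 ± 0.55 and Pecam1 by 1.47 ± 0.49.

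Luminal urothelial genes, which mark the differentiated bladder lining, were lower in non-responsive tumours, with 14 of 16 below 0 and a median of -1.68 (camera adjusted p = 7.51e-09; adjusted p = 0.539 with an estimated correlation). Adjusted over the list alone 5 passed, and 0 over all genes. Pparg, a regulator of luminal differentiation, was at 24.8 ± 12 against 103 ± 33.0 CPM (-2.05 ± 0.41). The tight junction gene Cldn4 differed by -1.49 ± 0.36, Krt18 by -2.26 ± 0.57, and the uroplakin genes Upk3a and Upk2 by -3.42 ± 0.88 and -2.89 ± 0.87, with -1.69 for Upk2 without responsive replicate 3. The luminal scores were -0.22, -0.99 and -1.24 in the non-responsive and -0.18, 0.98 and 1.65 in the responsive tumours.

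Mast cell markers had a median of -1.86, with 8 of 9 below 0 (camera adjusted p = 0.000589; adjusted p = 0.539 with an estimated correlation) and 5 past the threshold adjusted over the list alone. The mast cell score of non-responsive replicate 2 was 0.087, within the responsive range of -0.049 to 0.87. The mast cell proteases Tpsb2, Cma1 and Mcpt4, which have close paralogs, differed by -2.13 ± 0.52, -2.29 ± 0.60 and -2.22 ± 0.67, and the IgE receptor gene Fcer1a by -1.93 ± 0.65. Without responsive replicate 1 Mcpt4 differed by -1.45. In the other direction the stem cell factor receptor gene Kit differed by 1.6 ± 0.61 (unadjusted p = 0.0345), and by 0.96 without non-responsive replicate 2. Adipocyte markers had a median of -3.81 (camera adjusted p = 5.11e-06; adjusted p = 0.539 with an estimated correlation), and 9 of 10 passed adjusted over the list alone. The adipocyte genes had an estimated correlation of 0.936, so the 9 are not separate observations. DESeq2 called 0 of them, and the groups did not overlap for only 2 of the 10. Responsive replicate 1 had an adipocyte score of 4.21, against -2.99 to 0.86 in the other tumours. Without responsive replicate 1 the median was -1.09 (adjusted p = 0.000603). Pck1, Cfd, Retn and Fabp4, all expressed in fat tissue, differed by -4.24 ± 1.33, -4.12 ± 1.35, -4.47 ± 1.47 and -2.94 ± 0.99, and by -1.88, -1.80, -1.92 and -0.88 without responsive replicate 1. Skeletal muscle markers had a median of -1.38 (camera adjusted p = 0.00172; adjusted p = 0.486 with an estimated correlation), and -2.11 without non-responsive replicate 1 (adjusted p = 0.00545), with too few genes left to test under the stricter filter. The muscle genes Acta1, Tnnt3, Mylpf and Ckm differed by -1.38 ± 0.39, -2.77 ± 0.98, -2.91 ± 1.36 and -1.38 ± 0.86, and without responsive replicate 1 Tnnt3 by -1.38 and Mylpf by 0.10. Ckm differed by -0.40 without responsive replicate 3 and -0.88 without non-responsive replicate 3.

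Proliferation genes were higher in non-responsive tumours, with all 18 above 0 and a median of 0.54 (camera adjusted p = 3.51e-06; adjusted p = 0.539 with an estimated correlation), which was 0.29 without responsive replicate 3 (adjusted p = 0.0041). Mki67, a marker of dividing cells, was at 157 ± 47.1 against 54.6 ± 11.1 CPM (1.52 ± 0.29) and Top2a differed by 1.32 ± 0.32, both past the threshold adjusted over the list alone. The spindle motor Kif11 differed by 0.94 ± 0.26 and Rrm2 by 0.75 ± 0.29. Oxidative phosphorylation genes had a median of -0.37, with all 15 below 0 (camera adjusted p = 0.00144; adjusted p = 0.582 with an estimated correlation), and -0.29 without responsive replicate 1 (adjusted p = 0.0609). Cox5a, Ndufb8, Sdha and Cox4i1 differed by -0.59 ± 0.21, -0.88 ± 0.37, -0.68 ± 0.31 and -0.62 ± 0.30, with -0.40 for Sdha without responsive replicate 1 and -0.40 for Cox4i1 without non-responsive replicate 2. Immediate early and heat shock genes, which respond to tissue handling, had a median of -0.65, with 11 of 12 below 0 (camera adjusted p = 0.00974; adjusted p = 0.582 with an estimated correlation). It was -0.51 without non-responsive replicate 2 (adjusted p = 0.0694) and -0.33 without responsive replicate 2 (adjusted p = 0.107). Dusp1, Zfp36, Ier2 and Fos differed by -0.96 ± 0.45, -0.65 ± 0.37, -0.34 ± 0.22 and -0.76 ± 0.50. Without responsive replicate 2 Dusp1 differed by -0.61, Zfp36 by -0.40 and Fos by -0.040, and Ier2 differed by -0.17 without non-responsive replicate 2.

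**Figure D3:**
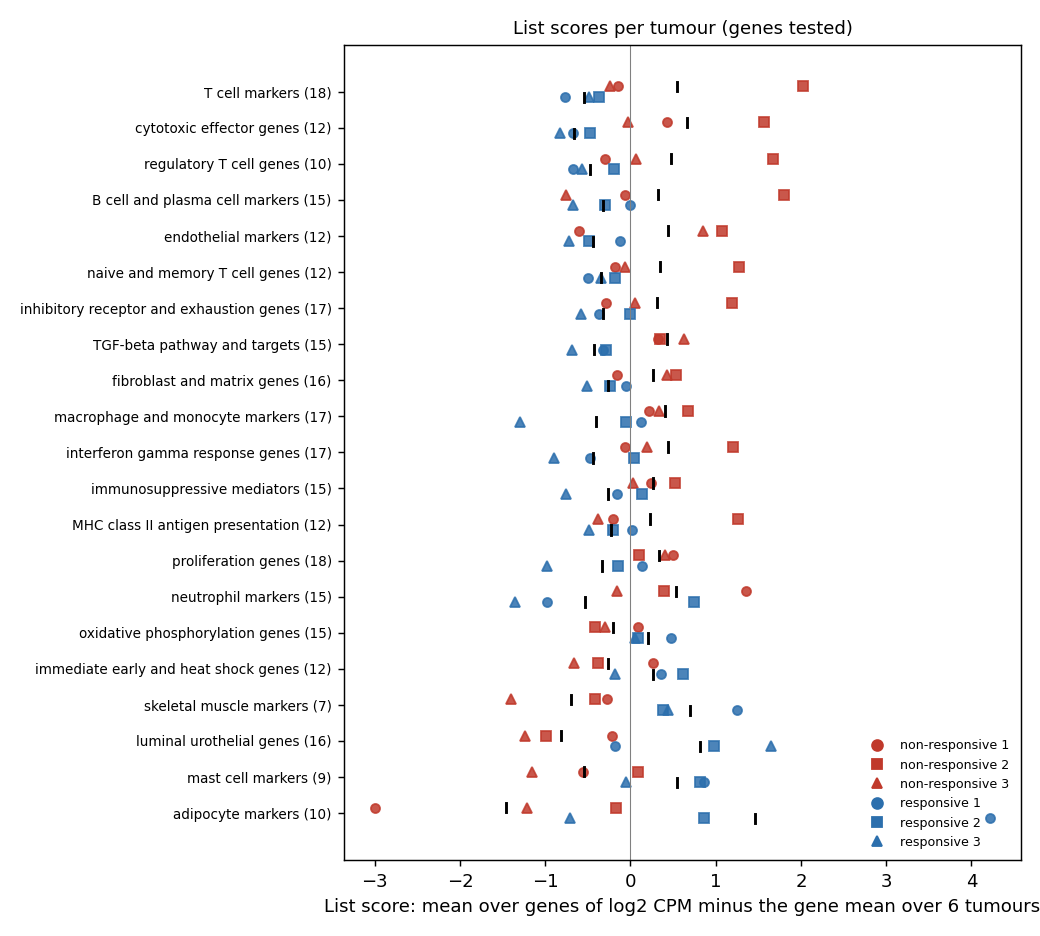
Score of each tumour (horizontal, mean over genes of log2 CPM minus the gene's mean over 6 tumours) for the 21 lists past the camera threshold, with the number of genes tested in brackets. Colours mark the response group, shapes the replicate number and black bars the group means; non-responsive replicate 2 has a T cell score of 2.02 and responsive replicate 1 an adipocyte score of 4.21.

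The other 10 lists did not pass the camera test. Dendritic cell markers had a median of 0.86 (adjusted p = 0.0655) and passed without non-responsive replicate 1 (1.08, adjusted p = 0.0361), without non-responsive replicate 3 (1.12, adjusted p = 0.000145) and without responsive replicate 1 (0.90, adjusted p = 0.0456). Without non-responsive replicate 2 their median was 0.27 (adjusted p = 0.943). Inflammatory cytokines had a median of 0.28 (adjusted p = 0.0768) and passed without non-responsive replicate 2 (0.42, adjusted p = 0.0488), non-responsive replicate 3 (0.58, adjusted p = 0.00599), responsive replicate 1 (0.19, adjusted p = 0.0192) and responsive replicate 2 (1.13, adjusted p = 0.000565). It was -0.37 without non-responsive replicate 1 (adjusted p = 0.723) and -0.16 without responsive replicate 3 (adjusted p = 0.978). Erythroid markers had a median of -2.15 (adjusted p = 0.142), with a score of 3.43 in responsive replicate 1, and passed without non-responsive replicate 3 (-3.57, adjusted p = 0.00239), responsive replicate 2 (-2.45, adjusted p = 0.0153) and responsive replicate 3 (-2.46, adjusted p = 0.0136). Without responsive replicate 1 the erythroid median was 0.98 (adjusted p = 0.377). MHC class I genes had a median of 0.11 (adjusted p = 0.306) and passed without non-responsive replicate 3 (0.40, adjusted p = 0.0139), while it was -0.063 without non-responsive replicate 1, -0.024 without non-responsive replicate 2 and -0.046 without responsive replicate 3. Lymphoid aggregate genes had a median of -0.23 (adjusted p = 0.308) and passed without non-responsive replicate 2 (-0.24, adjusted p = 0.00109), with 0.031 without non-responsive replicate 1. Smooth muscle markers had -0.28 (adjusted p = 0.391) and passed without responsive replicate 1 (-0.70, adjusted p = 0.00205), with 0.069 without non-responsive replicate 3 and 0.33 without responsive replicate 3. Schwann and nerve markers had a median of -0.04 (adjusted p = 0.460), with -0.78 without non-responsive replicate 2 (adjusted p = 0.0237) and medians above 0 without non-responsive replicate 1 (0.16), non-responsive replicate 3 (0.32), responsive replicate 1 (0.00018) and responsive replicate 3 (0.33). Hypoxia and glycolysis genes had 0.05 (adjusted p = 0.963), with 0.42 without non-responsive replicate 2 (adjusted p = 0.0307), and medians below 0 without non-responsive replicate 1 (-0.19), non-responsive replicate 3 (-0.016) and responsive replicate 3 (-0.12). Type I interferon response genes had a median of 0.06 and a mean of -0.00037 (adjusted p = 0.963), with a median of 0.26 without responsive replicate 2 (adjusted p = 0.0464), -0.00055 without responsive replicate 1 and -0.15 without responsive replicate 3. Basal and squamous genes had a median of 0.45 (adjusted p = 0.988) while the mean score differed by -0.11. They were lower without non-responsive replicate 1 (-0.86, adjusted p = 0.0166) and higher without non-responsive replicate 2 (0.86, adjusted p = 0.0152). Krt5, a basal keratin, differed by 0.66 ± 0.74, by -0.66 without non-responsive replicate 1 and by 1.11 without non-responsive replicate 2.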

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

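The likelihood ratio test, the FPKM fit, DESeq2 without each tumour and the single lists were chosen after the data were seen. The counts of 0 genes higher and 0 lower by edgeR also came out at 0 with DESeq2 size factors, upper quartile scaling, either other filter, limma-voom, FPKM and every tumour left out. The minimum fold of 2 only removes calls from the main result, so it could give nothing but 0. DESeq2 gave 217 higher and 230 lower and the likelihood ratio test 98 and 114. Of 97 genes named before members against a list's direction or of little difference were added, 93 kept their sign in every setting that gave a value, and 38 passed with DESeq2. Most of the 97 were named for a small p in these same data, which raises both counts by itself. The expression filter left Ifng untested, with counts of 6, 22 and 12 against 0, 5 and 2. The planned pseudocounts of 0.1 and 0.01 were for normalised values as the main data and were not run, since counts were the main data.

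The replicate block gave 0 genes higher and 0 lower and 22 lists. Same-numbered tumours had deviation correlations of -0.11, -0.09 and -0.02, and other pairs of -0.12 to 0.19, which gave no sign of pairing. With 3 tumours per group, each centred on its group mean, this check cannot exclude pairing.

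The count of 21 lists was 12 of 26 testable lists with the stricter filter, which leaves fewer genes, 0 with an estimated correlation and 0 by fry, which does not compare a list with other genes. Without a filter 23 lists passed, the dendritic cell (camera adjusted p = 0.0427) and inflammatory cytokine (0.0487) lists among them. The dendritic cell list also passed by camera on ranks (adjusted p = 0.0411). The stricter filter left the T cell, cytotoxic, regulatory T cell and skeletal muscle lists untestable and ended the calls of the inhibitory (adjusted p = 0.125), naive and memory T cell (0.0582), B cell (0.0525), MHC class II (0.0537) and immunosuppressive (0.251) lists. Leaving out 1 tumour gave 17 to 25 lists and, for DESeq2, 169 to 1966 genes. The cause of these differences was not tested.

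With 1 tumour left out the sign turned for 4 of these genes. The log2 fold change of Mylpf was between -3.49 and 0.10, of H2-DMb2 between -0.016 and 1.33, of Cd4 between -0.050 and 1.65 and of Krt5 between -0.66 and 1.11, and Krt5 was at -0.075 with limma-voom. The median also turned for 10 lists, of which MHC class II (-0.28 to 0.84) had passed camera. The other ranges were -0.41 to 0.031 for lymphoid aggregate genes, -0.15 to 0.26 for type I interferon, -0.063 to 0.40 for MHC class I, -0.70 to 0.33 for smooth muscle, -0.86 to 0.86 for basal and squamous, -0.19 to 0.46 for hypoxia, -0.37 to 1.13 for inflammatory cytokines, -0.78 to 0.33 for Schwann and nerve and -3.57 to 0.98 for erythroid genes. The cause was not tested.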

Other observations

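The T cell tests, the counts of scores within the responsive range, the likelihood ratio test and the gene families were chosen after the results were seen; the counts over splits, the position of each left-out tumour and the bounds for the overlap of the DESeq2 calls were set before their values were seen, while the interval around that overlap was added after.

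Beyond the lists, 14 gene families were picked by symbol after the gene differences were seen, and p-values were adjusted over these families only. The family p-values are therefore descriptive and give no separate evidence of a difference. No member of them passed edgeR over all genes, so counts above or below 0 give the sign of the log2 fold change only. Of 37 collagen chains 29 were above 0 and 10 were DESeq2 calls. The collagen median was 0.87 (camera adjusted p = 1.11e-09, and adjusted p = 0.0736 with an estimated correlation). Of 29 ADAM and ADAMTS proteases, which cut matrix and cell surface proteins, 22 were above 0 and 8 were DESeq2 calls. The protease median was 0.54, or 0.34 without non-responsive replicate 2 (camera adjusted p = 1.99e-05 with all 6 tumours, and adjusted p = 0.133 with an estimated correlation). Of 23 glutathione transferases, detoxification enzymes that include close paralogs, 20 were below 0 and 6 were DESeq2 calls. The glutathione transferase median was -1.39 (camera adjusted p = 3.01e-12, and adjusted p = 0.0631 with an estimated correlation). Major urinary protein genes, near-identical copies whose single counts are uncertain, had a median of -5.21 over 5 genes (camera adjusted p = 2.42e-06; adjusted p = 0.133 with an estimated correlation), with a score of 4.38 in responsive replicate 1, the tumour with the highest adipocyte score, and without it the median was -3.04. Immunoglobulin V segments had a median of 2.28 over 68 genes (camera adjusted p = 2.39e-08; adjusted p = 0.266 with an estimated correlation), with a score of 2.69 in non-responsive replicate 2, without which the median was 0.28. Of 26 late cornified envelope and small proline-rich genes of squamous epithelium 24 were below 0 and 4 were DESeq2 calls. The median of this family was -1.61 (camera adjusted p = 4.7e-12, and adjusted p = 0.116 with an estimated correlation). Integrins had a median of 0.76 with 16 of 22 above 0 (camera adjusted p = 2.6e-05). Lysyl oxidases had 0.98 with 4 of 5 above 0 (camera adjusted p = 0.000909), or 0.64 without non-responsive replicate 3. The p200 interferon-inducible genes had 0.65 with 9 of 11 above 0 (camera adjusted p = 1.14e-05), or 0.36 without responsive replicate 3. With an estimated correlation the adjusted p of integrins, lysyl oxidases and p200 genes was 0.116, 0.116 and 0.135. Aldehyde dehydrogenases had a median of -0.42 with 15 of 20 below 0 (camera adjusted p = 0.000805), or -0.87 without non-responsive replicate 1. Claudins had a median of -0.31 with 11 of 15 below 0 (camera adjusted p = 0.0116), or -0.66 without responsive replicate 2 and -0.58 without non-responsive replicate 2. With an estimated correlation both had an adjusted p of 0.116. Large-subunit ribosomal protein genes had a median of -0.30 with 45 of 48 below 0 and 0 DESeq2 calls (camera adjusted p = 0.000128, and adjusted p = 0.523 with an estimated correlation). The ribosomal median was -0.75 without non-responsive replicate 1, -0.078 without non-responsive replicate 2 and -0.20 without non-responsive replicate 3. Keratins had a median of -0.46 with 14 of 24 below 0 (camera adjusted p = 0.0378, and adjusted p = 0.523 with an estimated correlation). The keratin median was -1.19 without non-responsive replicate 1, -0.084 without non-responsive replicate 2, -0.10 without non-responsive replicate 3, 0.20 without responsive replicate 1 and -0.026 without responsive replicate 2. Cytochrome P450 genes had a median of -0.13 over 32 genes and did not pass (camera adjusted p = 0.142), with -0.16 to -0.27 when 1 tumour was left out. The 6 tumours can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In 10 of the 10 splits edgeR called 0 genes, the highest other split also at 0. DESeq2 called 447 genes in the real split and at most 307 in another, so 1 split reached the real value. Camera called 21 lists in the real split and at most 22 in another, and 3 splits reached the real value.

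T cell markers were higher in non-responsive tumours with a median log2 fold change of 1.47. A lower share of urothelial cells would raise other cell types alike, but the T cell score minus the mast cell score differed between the groups by 2.17 (SE 0.569), with mast cells lower. Both list differences were known before this test was chosen, and the T cell difference rested on non-responsive replicate 2. The test therefore cannot decide whether that share was the source. The T cell call depended on 1 lymphocyte-rich tumour, non-responsive replicate 2. Without it the median was 0.36 and the camera adjusted p = 0.0784, while the list passed in 5 of the 6 fits that left out 1 tumour. With an estimated correlation the call was also lost with all 6 tumours (adjusted p = 0.582).

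Non-responsive replicate 1 correlated most with responsive replicate 2 (Pearson r = 0.950). With responsive replicates 1 and 3 its r was 0.914 and 0.916, below the 0.921 with non-responsive replicate 3. Its position was taken on the 500 genes that best separated the other 5 tumours, with 0 at the responsive and 1 at the non-responsive mean. Non-responsive replicate 1 lay at 0.185, below the highest left-out responsive tumour at 0.541. A wrong response label on this tumour is a candidate explanation, but left-out positions were imprecise, with 0.352 to 0.541 for responsive tumours and 0.516 and 0.716 for the other non-responsive ones. Its score lay within the responsive range for 9 of the 21 lists that passed camera, endothelial, matrix and interferon gamma genes among them, against 4 and 3 lists for non-responsive replicates 2 and 3, while its TGF-beta score of 0.33 lay above the highest responsive score of -0.28. Variation among tumours that did not respond was not tested and stays open.

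DESeq2 called 447 genes and the edgeR quasi-likelihood test 0. In 408 of the DESeq2 calls (91.3%, Wilson 95% interval 88.3 to 93.6%) the groups did not overlap, against 17.7% of all tested genes and 10% by chance for any gene, but the calls had been selected for a group difference, which raises this share by itself. The bound set beforehand for excluding calls that rest on 1 extreme tumour was over 90%, which lies inside that interval, so for both reasons this test leaves that explanation open. The uncertainty in each gene's spread, which the quasi-likelihood test counts, is a candidate explanation, since the likelihood ratio test, which leaves it out, called 203 of the same genes. In simulated data of this size DESeq2 made 58 false calls and edgeR 8, so part of the 447 could be false.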
